A study of Mus musculus with 6 samples.

How the data were processed

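RNA-seq libraries of mouse osteoclasts were compared with and without verapamil. Per the labels' protocols, macrophages grown from tibial and femoral marrow in 30 ng/ml M-CSF were turned into osteoclasts with 50 ng/ml RANKL in medium holding 10% serum. The sample titles give day 5, whereas the protocol describes medium changes every 2 days up to day 7, so the day of harvest is uncertain. RNA was extracted with Trizol, and a SMARTER mRNA kit made each library from 1.3 ug of total RNA, per the labels' protocols. The labels give neither the dose of verapamil nor its timing, and they do not say whether the counting used strand.

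The table holds estimated counts of reads per gene, deposited by the authors with 2 decimals and, judged from the values, without normalization. It covers 16775 genes, of which 175 had no count in any library used. The builds GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the counting program and the annotation are not given in the sources used here. The table lists messenger RNA genes by Entrez identifier and symbol, and holds no mitochondrially encoded gene. Labels describe 6 libraries, 3 per group. Control replicate 2 was not analysed here, so 2 control libraries (replicates 1 and 3) were compared with 3 verapamil libraries. The test had been planned for 3 against 3 and was otherwise run as planned.

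Counts were rounded to whole numbers. In R 4.3.3, edgeR 4.0.16 scaled the libraries by TMM, kept genes by its default expression filter (minimum count 10, minimum total count 15), and fitted a quasi-likelihood model with the group as the only term. This left 12619 genes, 3 residual degrees of freedom and 3.28 prior degrees of freedom. The common dispersion corresponded to a biological coefficient of variation of 15.3%. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Values per library are CPM, counts scaled to the size of the library after TMM, as mean ± SD. Standard errors were derived from the edgeR test, as the absolute log2 fold change divided by the square root of its F statistic. They restate that test and are not separate evidence of precision. Cochran's test of the stromal markers used them as weights. Positive log2 fold changes mean higher values with verapamil.

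Before the data were examined, 33 gene lists were fixed, on osteoclast function, signalling, metabolism, stress and markers of other cell types the culture could hold. Each list with at least 5 tested members was tested with camera (limma 3.58.1), a two-sided competitive test of a list against all other genes, on log2 CPM (prior count 2) with a preset correlation of 0.01. The adjusted p over the 32 lists tested is given, followed by the adjusted p when the correlation was estimated for each list. With an estimated correlation camera works with the residual degrees of freedom of the fit, which are 3 here. That version therefore has little power whatever the correlation, and a call lost there cannot be put down to correlation between genes. Members were counted with p adjusted over all genes and again with p adjusted over the list alone. Genes to be named were also fixed by rule. The rule took the 5 largest rises and the 5 largest falls among called genes whose mean expression was at or above the median and whose groups did not overlap, without predicted genes. It added the 2 smallest p-values in each direction, up to 4 called members of each list past the threshold, the called member with the largest change of each other list, and 11 fixed genes. This gave 92 genes, not all of which are reported here. Any other gene named was chosen after its values were seen.

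Total estimated counts were 20202340 to 21494523 per library. Intervals of ratios of low genes are exact 95% binomial intervals of the summed counts, which cover counting error only. A test on simulated counts for verapamil against control (12397 genes in that step) recovered 12.2% of genes changed by 0.5 on the log2 scale, 61.2% at 1, 92% at 2 and 100% at 3. Of its 176 calls, 14 (7.95%) were false, which is above the nominal 5%. Far fewer genes were changed in the simulation than were called in the data, and its genes were drawn independently of each other. Its rates therefore need not hold for the real libraries.

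The replicate pairs were checked for repeated libraries. Differences between libraries exceeded Poisson noise in every pair within a group. The variance was from 2.1 times (verapamil replicates 2 and 3) to 40 times (the 2 controls) that of counting alone. Nothing in the labels says that the replicates of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

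Gene positions come from the RefSeq table of GRCm38, patch 6, in which 12558 of the 12619 tested identifiers were found. Shared exon bases were taken from GENCODE M21 on the same assembly with Python 3.11.15. Because strand use is not stated, reads of genes that share exon bases cannot be told apart. Members of families with similar sequences, such as the Slfn, Oas, Ifit and class II histocompatibility genes and Lyz2, are likewise uncertain where the counting divided shared reads.

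Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile factors, no filter on low counts, a stricter filter (1 CPM in every library of a group), the replicate number as a block, leaving out each library, the Wald test of DESeq2 1.42.0, limma-voom, camera with estimated correlations, and fry, which tests a list against no change rather than against other genes. Removal of each library's trend with transcript length was added after the data had been seen.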

Results

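RNA-seq was carried out on osteoclasts, the multinucleated cells that resorb bone, which had been differentiated from mouse bone marrow macrophages with the cytokines M-CSF and RANKL. The 3 verapamil libraries and 2 control libraries (replicates 1 and 3) held 20202340 to 21494523 estimated reads each. Verapamil is a blocker of L-type voltage-gated calcium channels. The comparison asked how the drug alters gene expression in differentiating osteoclasts.

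Verapamil-treated osteoclasts had lower levels of 6 genes for bone resorption and cell fusion (Acp5, Ctsk, Mmp9, Calcr, Dcstamp and Ocstamp). The lists of interferon response, antigen presentation and stromal marker genes were lower, and those of cholesterol synthesis and lysosome genes were higher, by camera with a preset correlation. With estimated correlations 0 lists passed (lowest adjusted p = 0.117). Acp5, which encodes tartrate-resistant acid phosphatase, fell from 2028 ± 156 CPM (SD, n = 2) to 562 ± 20.3 CPM (SD, n = 3). Lss, the lanosterol synthase of the cholesterol pathway, rose from 14.4 ± 3.35 CPM (n = 2) to 67.6 ± 2.56 CPM (n = 3). In edgeR's quasi-likelihood test, 3200 of 12619 genes changed (Benjamini-Hochberg adjusted p under 0.05), 1261 of them higher and 1939 lower with verapamil. At least 2-fold changes were found for 1688 genes, of which 341 were higher and 1347 lower. All 3200 genes had groups that did not overlap. Among all tested genes 7155 did so, which is 56.7% against 20% by chance.

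The count of changed genes varied with the libraries used. It was 7808 without control replicate 3, 4533 without control replicate 1, and 1485, 1565 and 1460 without verapamil replicates 1, 2 and 3. No gene called with all 5 libraries changed sign in any of these, which largely follows from the groups of these genes not overlapping. Without control replicate 1 or 3 only 1 control remained, so p-values of those fits, here and below, hold no spread between controls. Leaving out a verapamil library gave similar counts whichever it was, and left fewer residual degrees of freedom than the 3 of the main fit. A call lost in those fits, here and below, can therefore reflect lower power and does not by itself show that a result rested on 1 library. Upper quartile scaling shifted the median log2 fold change of all genes from -0.01 to -0.13 and the share of higher genes among the called ones from 39.4% to 28.2% (3246 calls). That share was 45.7% without control replicate 1, 51% without control replicate 3, 30.1% to 32.1% without a verapamil library, 45.4% with the transcript length trend removed and 46.7% with DESeq2's Wald test. The first principal component held 72.5% of the variance and separated the groups, and the second (16.8%) separated control replicate 1 from control replicate 3. These controls had a Pearson correlation of log2 CPM of 0.9718 across genes, and the verapamil pairs had 0.9913 to 0.9929. Between groups it was 0.9615 to 0.9627 for control replicate 3 and 0.9376 to 0.9467 for control replicate 1. Over 9724 genes the typical variance relative to counting was 40 between the controls. It was 18 to 18.6 between control replicate 3 and the verapamil libraries, and 56.6 to 72.5 for control replicate 1.

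Several genes of the resorption machinery list fell with verapamil. Mmp9, a secreted gelatinase, went from 2511 ± 236 CPM (n = 2) to 716 ± 38.5 CPM (n = 3), a log2 fold change of -1.81 (SE 0.106, edgeR adjusted p = 0.000437). For Acp5 the log2 fold change was -1.85 (SE 0.0975, adjusted p = 0.000437). Ctsk, the cathepsin that degrades bone collagen, decreased from 1961 ± 292 to 844 ± 31 CPM (log2 -1.22, SE 0.118, adjusted p = 0.00136). Mmp13, a collagenase, and Calcr, the calcitonin receptor, changed by -2.75 (SE 0.206, adjusted p = 0.000681) and -1.73 (SE 0.202, adjusted p = 0.0025). Mmp13 was low, at 16.25 ± 2.57 CPM in controls, and which cells expressed it was not measured. The genes of 2 membrane proteins needed for fusion of precursors fell as well, Dcstamp from 64.3 ± 8.1 to 20.8 ± 0.886 CPM (log2 -1.62, SE 0.121, adjusted p = 0.000676) and Ocstamp from 17.1 ± 1.33 to 4.25 ± 0.267 CPM (log2 -2.00, SE 0.132, adjusted p = 0.000543). On GRCm38, Acp5 (Entrez 11433) lies on chromosome 9 at 22126727 to 22135746, Mmp9 (17395) on chromosome 2 at 164940326 to 164955850 and Ctsk (13038) on chromosome 3 at 95499210 to 95509387. Dcstamp (75766) lies on chromosome 15 at 39745930 to 39760938, Ocstamp (74614) on chromosome 2 at 165395450 to 165400394 and Calcr (12311) on chromosome 6 at 3685678 to 3764713. Acp5 shares 6.75% of its exon bases with the transcript 6530413G14Rik.

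Other genes of the same lists moved the opposite way. Atp6v0d2, the proton pump subunit that also takes part in fusion, rose from 522 ± 43.1 to 1028 ± 16.9 CPM (log2 0.98, SE 0.0996, adjusted p = 0.00159). Clcn7, the chloride exchanger of the ruffled border, and Rab7, a GTPase of lysosomal transport, both chosen after their values were seen, rose by 0.52 and 0.47 on the log2 scale (adjusted p = 0.029 and 0.0146). Of 26 tested genes of the resorption machinery 6 were higher and 10 lower (7 and 13 when adjusted over the list alone), and camera did not call the list (median log2 -0.32, adjusted p = 0.18). Of 22 fusion genes 3 were higher and 6 lower (4 and 6 adjusted over the list alone; median -0.13, camera adjusted p = 0.437). With the length trend removed the fusion list passed as lower (median -0.31, adjusted p = 0.0372). Adam12, with the largest change in the latter list, rested on 40 counts in the controls and 5 with verapamil. Itgb3, the integrin of the sealing zone, had 110 ± 28.7 CPM in controls and 114 ± 7.44 CPM with verapamil (log2 0.05, SE 0.171, adjusted p = 0.838). Its estimate was -0.19 without control replicate 1 and 0.35 without control replicate 3, and -0.06 under upper quartile factors. Markers of macrophages and of stromal cells were also lower with verapamil, as described with those lists.

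**Figure D1:**
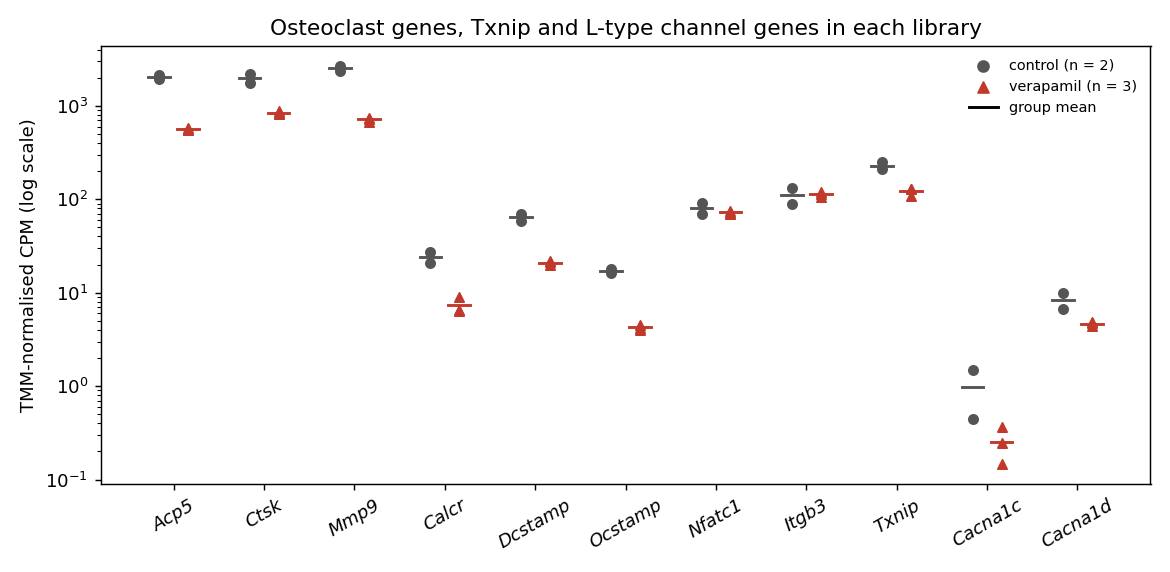
TMM-scaled CPM (log axis) of 11 genes fixed before the data were examined, in each of the 2 control libraries (circles) and 3 verapamil libraries (triangles), with horizontal lines at group means. Acp5, Ctsk, Mmp9, Calcr, Dcstamp and Ocstamp lie lower in every verapamil library than in either control, whereas the means of Itgb3 are 110 and 114 CPM.

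Among signalling genes, the transcription factor Fos, which is required for osteoclast formation, fell from 45 ± 1.82 to 6.56 ± 1.33 CPM (log2 -2.78, SE 0.171, adjusted p = 0.000472). Nfatc1, the calcium-dependent master regulator of osteoclast genes, had 80 ± 15.6 and 72.2 ± 2.51 CPM (log2 -0.15, SE 0.138, adjusted p = 0.449). Without control replicate 1 its log2 fold change was -0.33, and without control replicate 3 it was 0.07. With the transcript length trend removed it was -0.28 (adjusted p = 0.0207). In the list of RANK signalling and osteoclast transcription factors 4 of 39 genes were higher and 13 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.122). Negative regulators of osteoclast formation went both ways, 4 of 28 higher and 7 lower (5 and 8 adjusted over the list alone). Their median was 0.05, their mean -0.30, camera placed them lower and the adjusted p was 0.948. Id1, an inhibitor of helix-loop-helix factors, fell by 2.19 on the log2 scale (SE 0.298, adjusted p = 0.00411).

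The L-type channel genes were weakly expressed. Cacna1c had 0.972 ± 0.739 CPM (n = 2) and 0.252 ± 0.107 CPM (n = 3), from 45 and 15 counts in all, and did not pass the test (log2 -1.94, SE 0.642, adjusted p = 0.0733). Its estimate was -2.54 without control replicate 1 and -0.83 without control replicate 3. It was -2.23 with the length trend removed (adjusted p = 0.0106) and -2.21 with the replicate block (adjusted p = 0.00385). Cacna1d went from 8.3 ± 2.27 to 4.64 ± 0.233 CPM (log2 -0.84, SE 0.2, adjusted p = 0.0276), a call that was lost when any of verapamil replicates 1, 2 and 3 was left out (adjusted p = 0.109, 0.0942 and 0.0944). Its log2 fold change in those fits was -0.80, -0.86 and -0.87. Cacnb3, an auxiliary channel subunit, fell by 1.31 on the log2 scale (SE 0.146, adjusted p = 0.00213). Of 11 tested voltage-gated channel subunits 2 were lower and 0 higher, also when adjusted over the list alone (median -0.84, and -0.44 without verapamil replicate 1; camera adjusted p = 0.122, and 0.0198 with the length trend removed). Of 39 intracellular calcium signalling genes 5 were higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.534). Among them Atp2a3, a calcium pump of the endoplasmic reticulum, rose by 1.62 (SE 0.135, adjusted p = 0.000899). Txnip, the thioredoxin-interacting protein, decreased from 229 ± 26.3 to 122 ± 11.1 CPM (log2 -0.90, SE 0.124, adjusted p = 0.00421), and 19.4% of its exon bases are shared with the transcript Gm15441. In its list 2 of 18 genes were higher and 4 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.627), with the nuclear receptor Pparg higher by 1.26 (SE 0.103, adjusted p = 0.000865).

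Genes of cholesterol synthesis and SREBP2 targets rose together. Of 28 tested 24 were higher and 0 lower, also when adjusted over the list alone, with a median log2 fold change of 1.31 (camera adjusted p = 2.79e-14, and adjusted p = 0.117 with an estimated correlation). Lss rose by 2.23 (SE 0.169, adjusted p = 0.000699). Idi1 and Mvd, enzymes of isoprenoid synthesis, rose by 1.79 (SE 0.107, adjusted p = 0.000437) and 1.78 (SE 0.205, adjusted p = 0.0024). Among 18 LXR target and efflux genes 6 were higher and 4 lower (6 and 6 adjusted over the list alone; median 0.13, camera adjusted p = 0.43).

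Lysosome and autophagy genes were also higher, 26 of 58 against 1 lower (28 and 1 adjusted over the list alone), by a smaller median of 0.33 (camera adjusted p = 3.18e-06, and adjusted p = 0.146 with an estimated correlation). Gpnmb, a glycoprotein abundant in osteoclasts, rose from 9675 ± 621 to 26970 ± 480 CPM (log2 1.48, SE 0.103, adjusted p = 0.000598). Fnip2, a partner of folliculin, rose from 150 ± 20.9 to 485 ± 25.4 CPM (log2 1.69, SE 0.126, adjusted p = 0.000681), and the Rag GTPase Rragd rose by 1.39 (SE 0.136, adjusted p = 0.0014). The sulfatase Arsb was the member that fell (log2 -0.98, SE 0.185, adjusted p = 0.0128). That call was lost without verapamil replicate 1 or 3 (adjusted p = 0.0633 and 0.0612), and 32.3% of Arsb exon bases are shared with Gm26527. Of 19 proton pump subunits 4 were higher and 0 lower, also when adjusted over the list alone. Beside Atp6v0d2, the subunit genes Atp6v1c1, Atp6v1a and Atp6v0a1 rose by 0.80, 0.78 and 0.43 (adjusted p = 0.00223, 0.0142 and 0.0164), the last pair not past the threshold when any verapamil library was left out (adjusted p from 0.061 for Atp6v1a to 0.111 for Atp6v0a1). Atp6v0a1 did not pass under upper quartile factors (log2 0.31, adjusted p = 0.0508) or with the replicate block (adjusted p = 0.106) either. The camera call of the list was marginal (median 0.11, adjusted p = 0.0488, and adjusted p = 0.597 with an estimated correlation). The list's median was -0.03 without control replicate 3 and 0.3 without control replicate 1. The call was lost without verapamil replicate 1 or 3 (adjusted p = 0.124 and 0.0537). It was also lost with either other filter on low counts (adjusted p = 0.0501 with none and 0.0807 with the stricter one). Upper quartile factors (median -0.01, adjusted p = 0.101) and the replicate block (adjusted p = 0.0705) removed it as well. With the length trend removed the list passed as higher (median 0.195, adjusted p = 0.000833).

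Interferon-stimulated genes had the smallest camera p of the 32 lists. Of 46 tested 38 were lower and 0 higher (41 and 0 adjusted over the list alone), with a median of -1.90 (camera adjusted p = 5.14e-18, and adjusted p = 0.117 with an estimated correlation). The receptor chaperone Rtp4 fell from 36.2 ± 5.12 to 2.53 ± 0.723 CPM (log2 -3.83, SE 0.228, adjusted p = 0.000437) and the chemokine Cxcl10 from 17.3 ± 6.36 to 1.25 ± 0.205 CPM (log2 -3.78, SE 0.285, adjusted p = 0.000694). Slfn1 had 50 counts in the controls and 2 with verapamil, a ratio of 0.0305 with a 95% counting interval of 0.00359 to 0.116, and a log2 fold change of -4.81, or -4.29 without verapamil replicate 3. Oasl1 had 82 and 7 counts. Both belong to families of similar sequence.

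Inflammatory and antigen presentation genes were lower as well. Of 31 inflammatory cytokines and NF-kB targets 18 were lower and 4 higher (19 and 5 adjusted over the list alone; median -0.89, camera adjusted p = 0.000226, and adjusted p = 0.453 with an estimated correlation). The chemokine Ccl5 fell by 2.27 (SE 0.353, adjusted p = 0.0066), or by 1.56 without control replicate 1 and 2.74 without control replicate 3, and the cytokine Il1b fell by 2.18 (SE 0.386, adjusted p = 0.0103), while Il1a, chosen after its values were seen, rose from 4.56 to 19.1 CPM (adjusted p = 0.000767). Low-count members were Ccl12, with 72 and 10 counts, and Il10, with 42 and 8, whose call was lost without verapamil replicate 1 or 3 (adjusted p = 0.066 and 0.0507) and whose log2 fold change was -2.73, or -3.54 without verapamil replicate 2. Of 14 class II and dendritic cell markers 11 were lower and 1 higher, also when adjusted over the list alone (median -1.82, or -0.91 without a filter on low counts; camera adjusted p = 9.06e-06, and adjusted p = 0.117 with an estimated correlation). Cd74, the invariant chain of class II, fell from 61.2 ± 25.4 to 5.94 ± 0.699 CPM (log2 -3.36, or -2.85 without control replicate 1; SE 0.272, adjusted p = 0.000852), and the lectin Mgl2 from 33.2 ± 1.18 to 4.21 ± 0.371 CPM (log2 -2.98, SE 0.124, adjusted p = 0.000407). The class II chains H2-Eb1 and H2-Aa fell by 3.38 and 2.65 (adjusted p = 0.000877 and 0.00123). Itgax, chosen after its values were seen, was the member that rose (log2 1.08, adjusted p = 0.00335). Macrophage and stromal markers fell together with these lists and the interferon genes (medians -0.64 and -1.63).

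Macrophage markers fell in part. Of 28 tested 13 were lower and 3 higher (15 and 5 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 0.00771, and adjusted p = 0.171 with an estimated correlation). C1qa, a complement component, went from 944.5 ± 295 to 153 ± 7.3 CPM (log2 -2.63, SE 0.191, adjusted p = 0.000669), and the Fc receptor Fcgr1 from 53.6 ± 5.51 to 10.5 ± 1.05 CPM (log2 -2.36, SE 0.133, adjusted p = 0.000437). The folate receptor Folr2 fell by 3.51 (SE 0.171, adjusted p = 0.000437), with 63.1% of its exon bases shared with Gm10602. The chemokine receptor Cx3cr1 fell by 2.46 from 1.86 CPM (SE 0.316, adjusted p = 0.00339). The 3 members that rose, chosen after their values were seen, were the lysozyme Lyz2 (21450 to 37620 CPM, adjusted p = 0.00317), the receptor Mertk (adjusted p = 0.0404) and the lectin Clec7a (adjusted p = 0.00255).

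Markers of stromal cells and osteoblasts, which a marrow culture can carry over, were lower with verapamil. Of 22 tested 20 were lower and 0 higher (21 and 0 adjusted over the list alone), with a median of -1.63 (camera adjusted p = 4.91e-12, and adjusted p = 0.146 with an estimated correlation). The collagen gene Col3a1 fell from 32.2 ± 6.94 to 4.99 ± 0.235 CPM (log2 -2.69, SE 0.164, adjusted p = 0.000451). The osteoblast markers were near the detection floor, with 71 and 6 counts for Alpl, 90 and 9 for Bglap2, and 39 and 3 for Ibsp, whose ratio was 0.0586 (95% counting interval 0.0116 to 0.184). The log2 fold change of Ibsp was -3.94 with all libraries, -3.43 without verapamil replicate 2 and -4.79 without verapamil replicate 3, and that of Alpl was -3.88 and, without verapamil replicate 2, -3.35. The call for Bglap2 (adjusted p = 0.0441) was lost without control replicate 1 (log2 -1.95 against -3.68 with all libraries, adjusted p = 0.128) and without verapamil replicate 1, 2 or 3 (adjusted p = 0.0958, 0.127 and 0.117), and with limma-voom (adjusted p = 0.0904). In the list of erythroid, mast cell and basophil markers, 5 of 6 tested were lower and 1 higher, also when adjusted over the list alone (median -2.01, camera adjusted p = 0.0233, and adjusted p = 0.265 with an estimated correlation). Its members that moved include Pf4 and Ppbp, chemokines of megakaryocytes and platelets. Pf4 fell from 26.4 ± 8.86 to 0.784 ± 0.00759 CPM (log2 -5.06, SE 0.266, adjusted p = 0.000437), Ppbp fell by 2.85 (adjusted p = 0.00387) and the basophil protease Mcpt8 fell by 2.13 (adjusted p = 0.0084), whereas the receptor Kit rose by 2.24 (SE 0.214, adjusted p = 0.00131). This list's call was lost without control replicate 1 or 3 (adjusted p = 0.0542 and 0.0683), without a filter on low counts, under upper quartile factors, and with the length trend removed (adjusted p = 0.0997, 0.0694 and 0.0963).

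Proliferation genes were lower from a low level. Of 45 cell cycle genes 25 were lower and 1 higher (31 and 2 adjusted over the list alone; median -0.67, camera adjusted p = 5.23e-07, and adjusted p = 0.117 with an estimated correlation). The cyclins Ccnb2 and Ccna2 went from 3.46 and 6.69 CPM to 0.546 and 1.16 CPM, log2 fold changes of -2.64 and -2.52 (adjusted p = 0.00278 and 0.00463). Ube2c, a mitotic ubiquitin enzyme that shares 22.8% of its exon bases with Tnnc2, and Birc5, the survivin gene, fell by 2.52 and 2.13 (adjusted p = 0.00253 and 0.00255). Of 21 factors through which osteoclasts act on bone formation, 12 were lower and 2 higher (13 and 3 adjusted over the list alone; median -1.03, or -0.56 without control replicate 3; camera adjusted p = 0.00698, and adjusted p = 0.171 with an estimated correlation). Complement C3 went from 415 ± 73.2 to 64.7 ± 3.39 CPM (log2 -2.68, SE 0.133, adjusted p = 0.000437), the bone morphogenetic protein Bmp2 from 14 ± 1.13 to 4.91 ± 0.32 CPM (adjusted p = 0.00112) and Wnt10b from 123 to 21 counts (log2 -2.92, or -3.57 without verapamil replicate 2; adjusted p = 0.00491). Cthrc1 had 51 and 11 counts, and its call was lost without verapamil replicate 3 (adjusted p = 0.0544). These falls accompanied the lower stromal markers, whose genes include Col1a1 (log2 -1.47, adjusted p = 0.000743).

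**Figure D2:**
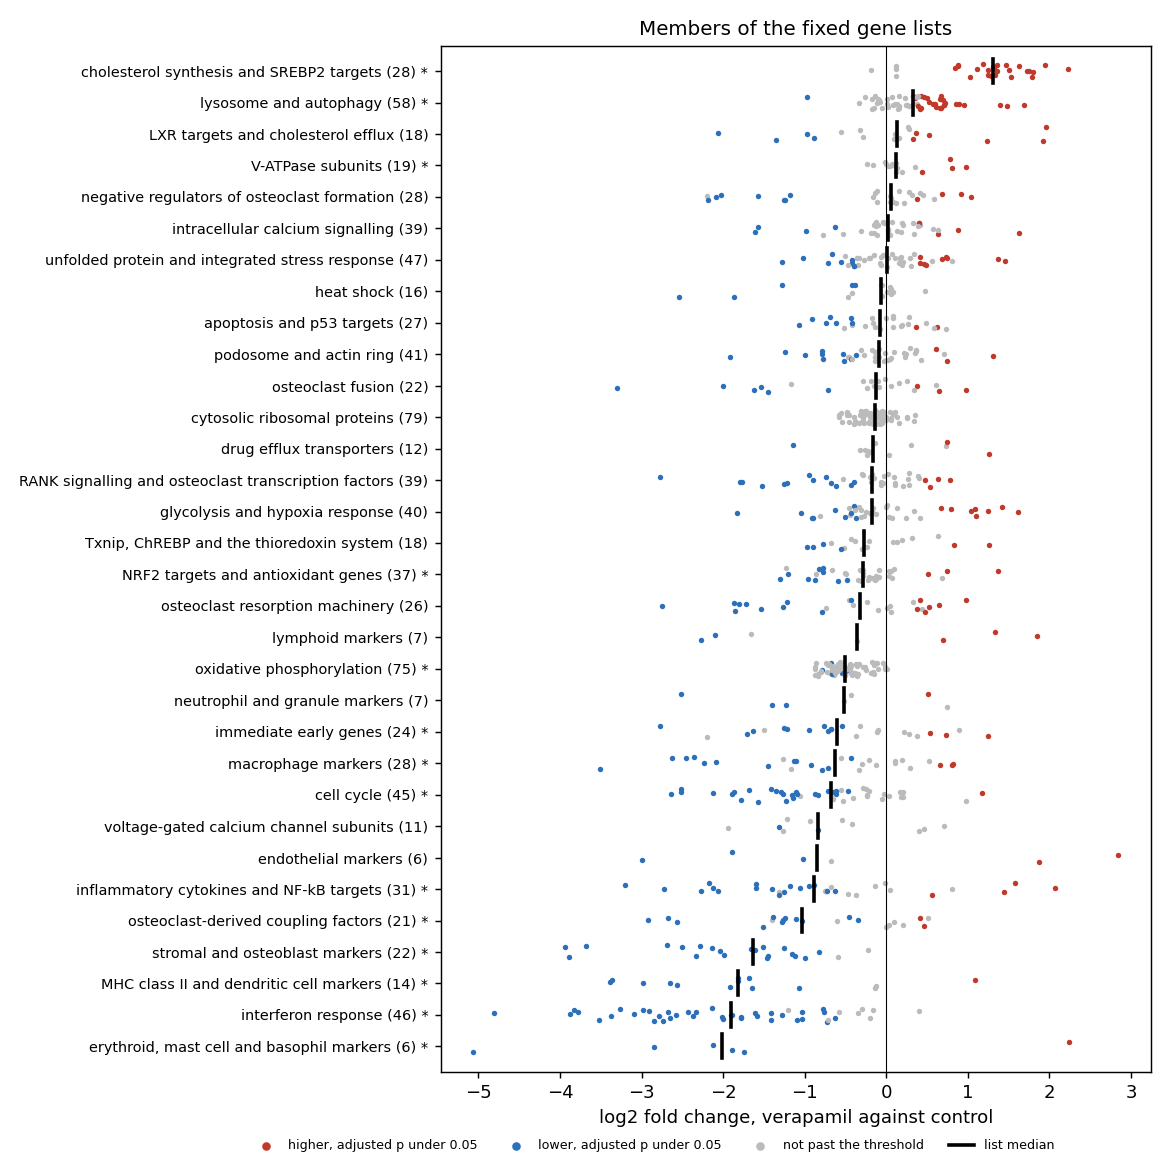
Log2 fold change with verapamil of each tested member (points) of the 32 lists tested, with the number of tested members in brackets, black bars at list medians and an asterisk at lists past a camera adjusted p of 0.05 with the preset correlation. Medians run from -2.01 for the erythroid, mast cell and basophil markers to 1.31 for cholesterol synthesis, and upper quartile factors turn the median of the V-ATPase subunits from 0.11 to -0.01.

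Several calls of lists on energy metabolism and stress were lost in alternative settings. Of 75 oxidative phosphorylation genes 5 were lower (0 adjusted over the list alone) and 0 higher (median -0.51, camera adjusted p = 7.09e-05, and adjusted p = 0.786 with an estimated correlation). Without control replicate 1 the median was -0.06, and without control replicate 3 it was -0.86. With the length trend removed it was -0.18 (adjusted p = 0.383). The subunit genes Atp5g3, Uqcrc1 and Cyc1 and the electron carrier Cycs fell by 0.79, 0.67, 0.54 and 0.67 (adjusted p = 0.0483, 0.0242, 0.0374 and 0.0229), and each call was lost when any of the verapamil libraries was left out (adjusted p from 0.079 for Cyc1 to 0.154 for Atp5g3). The call of Atp5g3 was also lost with DESeq2 size factors and limma-voom (adjusted p = 0.0516 and 0.0653). Without control replicate 1 these genes fell by 0.33, 0.41, 0.37 and 0.42, in the same order. Of 79 cytosolic ribosomal protein genes 0 were called by edgeR, with 2 at an unadjusted p under 0.05, 1 was called by DESeq2 and 0 by limma-voom. Their median was -0.14 (camera adjusted p = 0.905), 0.37 without control replicate 1 and -0.51 without control replicate 3, so its sign depended on which control was kept. Of 24 immediate early genes 11 were lower and 3 higher (14 and 3 adjusted over the list alone; median -0.61, camera adjusted p = 0.0155, and adjusted p = 0.597 with an estimated correlation), a call lost without control replicate 3 (adjusted p = 0.0568) and with the length trend removed (adjusted p = 0.0665), at medians of -0.60 and -0.53. Beside Fos, the early genes Egr1, Dusp5 and Klf2 fell by 1.63, 1.70 and 1.25 (adjusted p = 0.000543, 0.00364 and 0.0206), the last not past the threshold without verapamil replicate 1 or 2 (adjusted p = 0.0856 and 0.0778). Of 37 NRF2 target and antioxidant genes 9 were lower and 3 higher (13 and 4 adjusted over the list alone; median -0.29, camera adjusted p = 0.0289, and adjusted p = 0.624 with an estimated correlation), a call lost without control replicate 1 or verapamil replicate 2 (adjusted p = 0.173 and 0.0804), without a filter (adjusted p = 0.0501), with the replicate block (adjusted p = 0.246) and with the length trend removed (adjusted p = 0.76). Among them Slc7a11, the cystine transporter, rose by 1.37 (adjusted p = 0.00386), while Gstp1, Nqo1 and Prdx6 fell by 1.30, 1.21 and 0.96 (adjusted p = 0.01, 0.00324 and 0.00576).

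**Figure D3:**
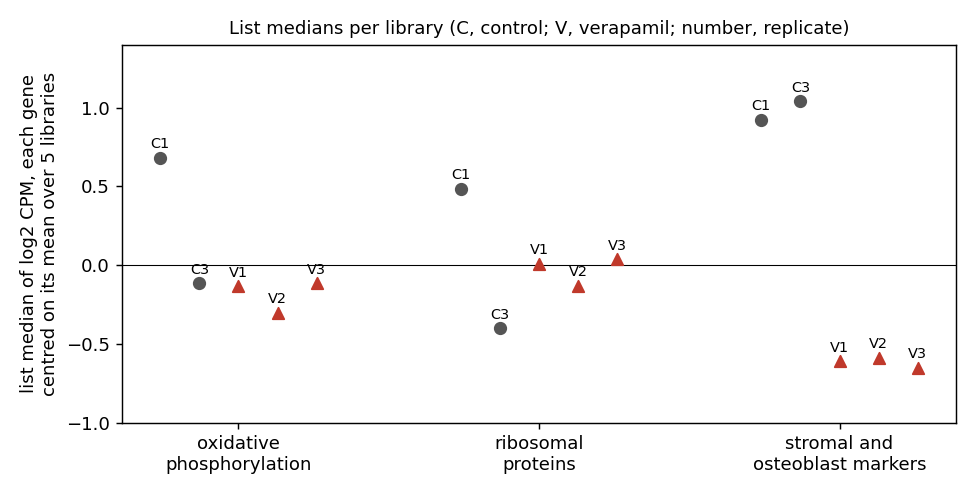
Median over each list of log2 CPM, with each gene centred on its mean over the 5 libraries, for control replicates 1 and 3 (circles) and verapamil replicates 1, 2 and 3 (triangles). Oxidative phosphorylation stands at 0.682 in control replicate 1, at -0.115 in control replicate 3 and from -0.301 to -0.115 with verapamil. The stromal list is at 0.923 and 1.04 in the controls and from -0.651 to -0.589 with verapamil.

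Camera did not call the other lists, whose members went both ways or passed in small numbers. Of 41 podosome and actin ring genes 3 were higher and 10 lower (4 and 12 adjusted over the list alone; camera adjusted p = 0.668), with the actin-bundling Fscn1 lower by 1.92 (adjusted p = 0.000471). For 40 glycolysis and hypoxia genes the counts were 8 higher and 9 lower (8 and 10 adjusted over the list alone; adjusted p = 0.896), and the vasodilator peptide Adm fell by 1.82 (adjusted p = 0.00472). Among 47 unfolded protein and integrated stress response genes 9 were higher and 9 lower, also when adjusted over the list alone (adjusted p = 0.788), and Gadd45a, a growth arrest gene with 19.1% of its exon bases shared with E230016M11Rik, rose by 1.45 (adjusted p = 0.00214). Of 27 apoptosis and p53 genes 2 were higher and 7 lower (5 and 7 adjusted over the list alone; adjusted p = 0.788), with Eda2r at -1.07 (adjusted p = 0.0454, and 0.0505 to 0.149 when control replicate 3 or any verapamil library was left out), at -0.51 without control replicate 3, and not past the threshold with limma-voom (adjusted p = 0.0675). Heat shock genes were lower in 5 of 16 and higher in 0, also when adjusted over the list alone (adjusted p = 0.16), led by the small chaperone Hspb1 at -2.54 (adjusted p = 0.00123). Of 12 drug efflux transporters 2 were higher and 1 lower (3 and 1 adjusted over the list alone; median -0.16, mean 0.05, direction by camera higher, adjusted p = 0.972). Abcb1a, which encodes the pump P-glycoprotein, had a log2 fold change of 1.26 (adjusted p = 0.0363, and 0.104 to 0.123 when any of the verapamil libraries was left out). It was 0.82 without control replicate 1 and 1.94 without control replicate 3.

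Marker lists of further cell types were small. Of 7 tested neutrophil markers 1 was higher and 3 lower, also when adjusted over the list alone (median -0.52, camera adjusted p = 0.383; median -1.16, adjusted p = 0.0284 without a filter on low counts), and S100a9 had 88 counts in controls and 20 with verapamil. Of 7 lymphoid markers 3 were higher and 2 lower (3 and 3 adjusted over the list alone), with a median of -0.36 while camera placed them higher (adjusted p = 0.896). Of 6 endothelial markers 2 were higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.801). Pecam1 had 106 and 17 counts, and its call (adjusted p = 0.0142) was lost without verapamil replicate 1 or 3 (adjusted p = 0.0524 and 0.0599). Its log2 fold change was -3.00, and -4.17 without verapamil replicate 2. The apolipoprotein gene Apoc1, an LXR target, had 77 and 24 counts.

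Among called genes with mean log2 CPM at or above the median of all tested genes, the largest rise was that of Dio2, the deiodinase that activates thyroid hormone, from 12.7 ± 1.64 CPM (n = 2) to 217 ± 24.8 CPM (n = 3). Its log2 fold change was 4.09 (SE 0.168, edgeR adjusted p = 0.000407), and it lies on chromosome 12 at 90724552 to 90739038. Cdkn1c, a cyclin-dependent kinase inhibitor, rose from 29.7 ± 4.33 to 372 ± 15.1 CPM (log2 3.65, SE 0.139, adjusted p = 0.000407). Of its exon bases 30.7% are shared with Gm44732. Mgll, the monoglyceride lipase, rose from 53.6 ± 2.39 to 480 ± 15.7 CPM (log2 3.16, SE 0.105, adjusted p = 0.000407). Bex1 and Gprc5b rose by 3.58 and 2.45 (SE 0.189 and 0.134, adjusted p = 0.000437 for both). Within the same expression limit the largest falls were those of Ly6e, a membrane-anchored protein induced by interferon, from 236 ± 74.1 to 22.4 ± 1.55 CPM (log2 -3.40, SE 0.202, adjusted p = 0.000437), Tmem176a (log2 -2.77, SE 0.172, adjusted p = 0.000481) and the tropomyosin Tpm2 (log2 -2.72, SE 0.189, adjusted p = 0.000598), followed by C3 and C1qa. The smallest p-values among falling genes belonged to Fcrls, an Fc receptor-like gene of macrophages (43.9 ± 0.297 to 3.74 ± 0.494 CPM), and Ccn2, a matricellular protein (98.2 ± 8.07 to 16.2 ± 0.437 CPM). Both had an adjusted p of 0.000407, and Ccn2 shares 23.2% of its exon bases with Gm15270.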

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

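Every alternative was fixed before the data were examined except the removal of the transcript length trend, which was added after they had been seen. With 2 against 3 libraries, 1 control decides part of every value, and at the depth of these libraries genes under about 1 CPM have wide counting intervals. The count of changed genes (3200) stayed within 1.5 times under every other scaling, filter and test, with 3404 for DESeq2, 3189 for limma-voom, and 2987 without a filter, and 82.3% to 99.1% of the 3200 genes kept their call in these and under the replicate block. It rose to 4912 with the length trend removed, of which 2230 were higher. Leaving out a library gave 1460 to 7808 changed genes, 440 to 3983 higher and 1009 to 3825 lower, and at least 2-fold changes in 1177 to 2399 genes, 270 to 873 higher and 896 to 1526 lower. Fits without a control assume that the lone control varies like the verapamil libraries. Of the 14 lists called, 0 passed with estimated correlations (lowest adjusted p = 0.117), and 20 of 32 lists passed fry's directional test and 30 its mixed test, which ask whether a list changed at all and not whether it differs from other genes. Interferon, cholesterol, stromal, cell cycle, lysosome, class II, inflammatory, coupling factor and macrophage lists passed in 13 of 14 settings, all but the estimated correlation. With the replicate block 3317 genes were called. Verapamil replicate 2 has no control of its number, so that block compares replicates 1 and 3 only. It leaves fewer residual degrees of freedom than the 3 of the main fit, and its p-values carry little weight. The labels share the numbers 1 and 3 and say that pairs were repeated without saying what a pair shares. Deviations from the group means correlated at 0.289 for replicates 1 and 0.0224 for replicates 3, and also at 0.289 for control replicate 3 with verapamil replicate 2. With 2 controls the deviations of one mirror those of the other, so these correlations cannot show whether the numbers mark pairs. The samples are treated as sharing only a number, because the labels do not say what a pair shares. Under that block Cacna1c passed (adjusted p = 0.00385), Atp6v0a1, the V-ATPase list and the NRF2 list did not (0.106, 0.0705 and 0.246), and the direction given by camera turned for glycolysis (median -0.149), apoptosis (-0.0794), ribosomal proteins (-0.0269) and lymphoid markers (-0.211). Other turns of direction concerned results that had not been called, except oxidative phosphorylation. Of the single genes, Itgb3 turned to -0.0595 under upper quartile factors and -0.108 with the length trend removed, and ran from -0.187 to 0.347 when single libraries were left out, and Nfatc1 ran from -0.33 to 0.0662. For lists the direction is that of camera or fry, and the value is the list's median. Upper quartile factors turned drug efflux (-0.277) and endothelial markers (-0.976). No filter turned negative regulators (0.0684), glycolysis (-0.159) and ribosomal proteins (-0.127), and the stricter filter turned drug efflux (-0.18). Leaving out a library turned drug efflux (without control replicate 1, medians -0.219 to -0.0188 over the libraries left out), ribosomal proteins (without control replicate 1 or verapamil replicate 2, -0.514 to 0.366), negative regulators (without control replicate 3 or verapamil replicate 1, -0.0915 to 0.126), the unfolded protein response (without control replicate 3, -0.0726 to 0.0591), glycolysis (without verapamil replicate 2, -0.22 to -0.0678) and lymphoid markers (without verapamil replicate 3, -0.701 to 0.0726). Removal of the length trend turned oxidative phosphorylation (-0.177), calcium signalling (-0.0808), glycolysis (-0.144), drug efflux (-0.184) and ribosomal proteins (0.221, adjusted p = 2.22e-11). Fry turned glycolysis (-0.181) and endothelial markers (-0.851). The cause of these changes was not tested. Alternatives meant for normalized units do not apply to counts, and leaving out control replicate 2 was not run, because that library was not analysed here.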

Other observations

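Of the tests below, only the heterogeneity of the stromal fold changes and the GC trend were set down before their results were seen. All others, the gene lists on fatty acids, Pparg targets and contractile genes included, were chosen after the data had been seen.

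Fatty acid synthesis genes rose beside cholesterol synthesis. Of 19 tested 15 were higher and 1 lower, with a median log2 fold change of 0.628 (camera p = 1.09e-07, and adjusted p = 0.0592 with an estimated correlation). Fads2 and Fads1, desaturases of polyunsaturated fatty acids, rose by 2.11 (SE 0.121) and 0.61 (SE 0.0892), and Acaca, acetyl-CoA carboxylase, by 1.17 (SE 0.193). Of these genes 6 stand in the lists fixed earlier, and among the 13 others 10 rose and 0 fell, so a joint rise of both branches of lipid synthesis is one hypothesis these values are consistent with. The nuclear receptor Pparg rose too, but a hypothesis that its targets follow it met 7 of 23 targets that fell against 4 that rose. The target list did not pass camera's test (adjusted p = 0.294 over the 3 lists). Angptl4 fell by 3.10 (SE 0.142), Pdk4 by 1.93 (SE 0.197) and Lpl by 1.35 (SE 0.182), while Fabp4 rose by 1.22 (SE 0.225).

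Genes of the contractile cytoskeleton and targets of the mechanosensitive factors SRF and YAP fell together. Of 28 tested 21 were lower and 0 higher, with a median of -1.58 (camera p = 2.77e-12, and adjusted p = 0.0592 with an estimated correlation). The log2 fold changes of Ccn1, Myl9, Cnn1 and Actg2 were -2.32 (SE 0.129), -2.58 (SE 0.154), -2.89 (SE 0.254) and -2.79 (SE 0.144), while Srf itself was at -0.16 (adjusted p = 0.275). Without the 5 members of earlier lists and without Ccn2 and Tpm2, which had prompted the list, 15 of 21 fell (median -1.54). Stromal cells are known to express contractile genes, so a change in osteoclasts and a change in stromal cells both stay open.

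Acp5, Ctsk, Mmp9, Dcstamp, Ocstamp and Calcr were lower in every verapamil library than in either control. A lower share of osteoclasts among otherwise unchanged macrophages would have raised markers that macrophages express more than osteoclasts do. Of 28 macrophage markers 13 fell and 3 rose, which argues against that explanation only for markers lower in osteoclasts. The same explanation would lower every gene that osteoclasts express more than macrophages do. Of 26 resorption machinery genes 10 fell and 6 rose, and of 22 fusion genes 6 fell and 3 rose. The rises argue against a lower share alone only for genes with higher expression in osteoclasts. Expression in each cell type was not measured here. The choice among the 3 scalings did not account for the falls, because the log2 fold change closest to 0 over the 6 genes was -1.21. All 3 scale by the bulk of the genes, so they could not show a change in total RNA per cell. Against either control alone the log2 difference closest to 0 was -1.06, so the falls did not rest on just one of the controls used. The sign of this value was already given by the genes being lower than in either control, so only its size is added. It cannot show a bias shared by both controls, and the labelled control that was not analysed could not be checked. An effect of verapamil on the osteoclast programme stays open as a hypothesis, as do a change in the remaining macrophages and a difference in the stage of culture, which were not tested.

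Stromal and osteoblast markers fell although the culture was meant to hold macrophages and osteoclasts. Fewer stromal cells of a single kind with unchanged expression would give all markers the same fold change. Instead the log2 fold changes ran from -3.94 for Ibsp to -0.22 for Runx2. Their heterogeneity had a p of 1.7e-64 (Cochran's Q 365 over 22 genes), a test that wrongly treats genes of the same libraries as independent. Genes that macrophages also express would fall less under that explanation, yet the collagen genes Col3a1 and Col1a2 differed as well (-2.69, SE 0.164, and -1.15, SE 0.108). Stromal carry-over that varies from dish to dish cannot be told apart from a change with the drug. The list medians differed by at most 0.12 within a group and by at least 1.51 between groups, but the labels do not say that the replicates of a group came from separate dishes, and libraries from a shared dish would agree in any case. Loss of particular stromal cell types and lower expression within them were not tested and may both contribute.

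The controls differed from each other in oxidative phosphorylation genes, with a median log2 difference of 0.805 in favour of replicate 1, and in ribosomal protein genes (0.867). Across genes, which are not independent replicates, this difference had a Spearman correlation of -0.671 with transcript length, and the median difference was 0.61 for transcripts up to 1329 nt and -0.60 for those from 6719 nt. Removing the length trend left a median difference of 0.121 in oxidative phosphorylation genes and 0.251 in ribosomal protein genes (96.8% of tested genes had a length), which is consistent with a length bias between the libraries, whereas removing the GC trend left a difference of 0.829 in the former. The fold change between the groups was correlated with length as well (Spearman 0.275). Per library, deviations from each gene's mean correlated with length at -0.482 in control replicate 1. Control replicate 3 (0.224) lay within the range of the verapamil libraries (0.0446 to 0.388), so the trend between the groups rested on control replicate 1. The cause of that trend was not tested. A length bias may come from RNA quality or library preparation, and the labels give no record of either. No biological explanation was tested, since both libraries belong to the same group.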
